A study of mouse gut metagenome with 41 samples.

How the data were processed

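Stool was taken from the colon of male mice at dissection, at 4 months of age, per the labels' protocols. The 41 samples were 1 per mouse and fell into 8 groups by the labels' genotype and housing fields: 4 genotypes (WT, ApcMin, Tcf4Het and Tcf4Het ApcMin) in either non-enriched (NE) or environmentally enriched (EE) housing. NE groups had 4 mice each, 16 in all. EE groups had 7 WT, 8 ApcMin, 5 Tcf4Het and 5 Tcf4Het ApcMin mice, 25 in all. Per the labels' protocols, all dams were newly bought from one supplier, animals of every genotype stayed together until weaning, and each later cage held similar numbers of every genotype. DNA was extracted with a stool kit and a variable part of the bacterial 16S rRNA gene was amplified and indexed for Illumina sequencing, per the labels' protocols. The steps from reads to taxa (quality filters, clustering, reference taxonomy and any rarefaction) are not given in the sources used here.

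The authors deposited 4 tables, 1 per genotype, and no further tables were used here. Per the file headers, each row holds the mean relative abundance in NE and in EE, its SEM, the number of mice and a p-value. The means are a fraction of all sequences, as deposited by the authors, and summed to 1 within each rank of each group. Each table has 331 rows over 5 ranks: 12 for phyla, 26 for classes, 50 for orders, 92 for families and 151 for genera. These counts include rows that name no taxon. The same rows occur in all 4 tables. Fractions are printed here as percent. The test behind the deposited p is not named in the headers. The deposited p matched Welch's two-sided test computed from the deposited means, SEMs and mouse numbers, with a largest relative difference of 1.15% and a largest median of 4.11e-05% over the tables. It was listed as not determined in 66 rows for WT, 74 for ApcMin, 78 for Tcf4Het and 90 for Tcf4Het ApcMin, and both means were 0 in each of those rows. The table of the double mutant carries an abbreviation that was read as Tcf4Het ApcMin because the other 3 genotypes are named and the mouse numbers fit.

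Values per mouse and sequence counts were not used here, so the depth per sample is unknown and no counting interval is given. Diversity indices, count models and exact permutation tests between mice need values per mouse and were not run. Genotypes within a housing condition were set side by side without a test, as the design fixed before the data were examined set out for group means. Because group means were used, a share that is high in a single mouse cannot be seen directly, but 2 bounds follow from a mean and its SEM. A SEM equal to its mean shows that only 1 mouse of the group had a value above 0, and the mean of the mice left after dropping any 1 mouse lies within 1 SEM of the group mean.

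The design fixed before the data were examined foresaw a deposited adjusted p. The tables hold only unadjusted p-values, so Benjamini-Hochberg adjustment was computed from the deposited p over the genus rank, at a threshold of 0.05. The design did not fix the rank, and the genus rank was chosen, as the finest, after the files had been seen. The row of unassigned sequences, between 2.79% and 3.79% of each group, and the row of bacteria assigned no further, at most 0.0186%, name no taxon. They were left out of the tests after a first look that had included them, and the combined test called 2 genera either way. A genus row is named by its lowest assigned rank. An "unnamed" genus is a row with an empty genus field within its family, order or class, and it can hold several genera. The word "other" marks sequences the taxonomy left unresolved below that rank. Counts of genera below are counts of genus rows.

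Housing was compared over the 4 genotypes by turning each deposited p into a z signed by the direction of EE minus NE and combining the 4 z with equal weights (Stouffer's method), over the 78 genera with a p in all 4 tables. Mice of all genotypes shared cages, so the 4 tables can share cage effects and the combined p can then be too small. Genotypes were compared by the difference of 2 signed z over the square root of 2, with adjustment over all 530 tests of genera and genotype pairs. A signed z depends on group size and SEM, so this compares strength of evidence and not the size of a housing effect. For each of the 6 pairs of genotypes, log2(EE/NE) with a pseudocount of 8.85e-05% (the smallest mean above 0, over 2) was correlated across genera, against 10000 random pairings within 5 bins of mean abundance. Genera are not independent replicates. The closure factor is the EE over NE ratio of all that is not S24-7, and EE means and SEMs of all genera but S24-7 were divided by it. For 9 lists of taxa fixed before the data were examined, the mean signed z was set against 10000 random lists of the same size matched on mean abundance, which places a list among taxa and is no test between mice. Errors of log2 ratios come from the 2 SEMs by the delta method.

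Named taxa followed a rule fixed before the data were examined. It takes, per genotype, the taxa past the threshold or, with fewer than 3, the 6 with the smallest p. It adds those past the combined test, those at an unadjusted p under 0.05 in the same direction in 3 or more genotypes or in opposite directions in 2 genotypes, the 2 most abundant members of each list and the 3 most abundant genera. Other taxa named below were chosen after their values were seen.

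The functions were tested on simulated data before use: 20 sets of 4 tables for 78 genera, with the real mean abundances, between-mouse spreads and group sizes, independent genera, and 10 genera each raised 2-fold and 4-fold. The combined test called 41.5% of the genera raised 2-fold, 82% of those raised 4-fold and 0.776% of the unchanged ones. Single genotypes called between 3.5% and 11.5% of the genera raised 4-fold, and between 1% and 4% of those raised 2-fold. A raised genus had the same fold in all 4 genotypes, each genus had a single spread, and no cage effects were simulated. The rates need not hold for the real tables. Work was done in Python 3.11 with numpy, pandas and SciPy, and figures were drawn with matplotlib. Alternatives covered the abundance filter, the adjustment, the threshold, merged rows, the way of combining genotypes, the pseudocount, the list statistic and the centred log ratio. Added after the data were seen were the family rank, a log scale, the mean difference over genotypes, the return of the rows without a taxon, a threshold of 0.1 for the combined test, the combined test with the closure factor of S24-7 removed and a list without 2 gut lineages.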

Results

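The stool microbiota of 41 male mice was profiled by sequencing part of the bacterial 16S rRNA gene. Mice were wild-type (WT), carried the ApcMin allele, which gives rise to intestinal tumours, were heterozygous for Tcf4 (Tcf4Het), or carried both alleles. Each genotype was kept in non-enriched (NE) or environmentally enriched (EE) housing, with 4 NE mice per genotype and 7 WT, 8 ApcMin, 5 Tcf4Het and 5 Tcf4Het ApcMin mice in EE. The values are the authors' group means of relative abundance with their SEM over mice. The depth per mouse is unknown. Housing was compared within each genotype, and cages lay within a housing condition, so housing and cage cannot be told apart in these values.

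The community was made up mainly of Bacteroidetes, Firmicutes and Proteobacteria in all 8 groups. In WT mice the authors' deposited table gave Bacteroidetes 66.5% ± 4.37 (SEM) in NE and 61.8% ± 2.52 in EE, and Firmicutes 20.1% ± 2.80 in NE and 23.0% ± 3.35 in EE. Bacteroidetes had the lower mean in EE in 4 of 4 genotypes, with log2 ratios of EE over NE between -0.17 and -0.07. Actinobacteria, at 0.0619% on average, had the higher mean in EE in 4 of 4 genotypes. These were 2 of the 9 phyla with a ratio in every genotype, and neither direction was shared by all genotypes on the centred log ratio. With 4 genotypes the smallest two-sided exact sign-flip p is 0.125, so no phylum can pass on direction alone. In the combined test no phylum passed the adjusted threshold, and the smallest adjusted p was 0.284.

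**Figure D1:**
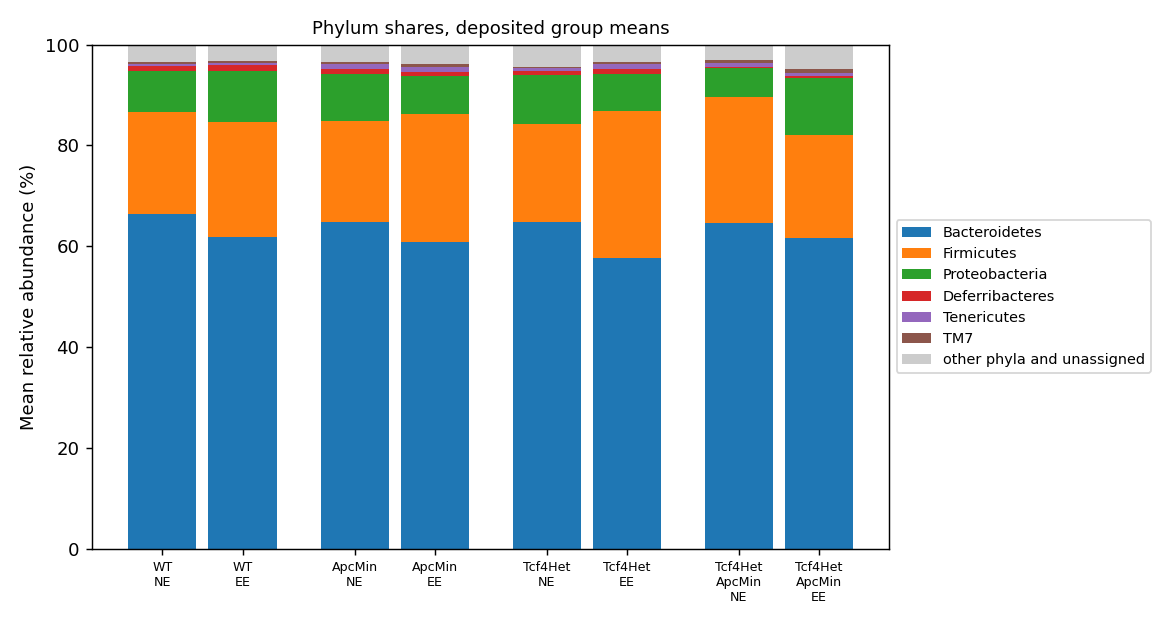
Stacked bars give the deposited mean relative abundance (%) of the 6 most abundant phyla in each of the 8 groups of genotype and housing. Bacteroidetes take the largest part of every bar, and their mean is lower in EE than in NE within each genotype.

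Cyanobacteria, which in mouse stool can be a gut lineage related to photosynthetic bacteria or DNA from food plants, differed between housing conditions in Tcf4Het ApcMin mice. The authors' deposited table gave 0.128% ± 0.0742 (SEM) in NE and 0.976% ± 0.117 in EE, 7.64-fold higher in EE, with p = 0.000658 and an adjusted p of 0.00592 over the 9 phyla of the authors' table. Almost all of it was the unnamed YS2 genus, a non-photosynthetic gut lineage, at 0.123% ± 0.0752 in NE and 0.974% ± 0.117 in EE. That genus did not pass over the genus rank, where its adjusted p was 0.0647, and passed among the genera above the median abundance (0.0465). Its lineage passed over the classes (0.0132), orders (0.0220) and families (0.0402) of the authors' table. These nested ranks hold nearly the same value, so they differ mainly in the number of rows adjusted over. The genus rank was chosen after the files had been seen. In the other genotypes YS2 had a higher EE mean in WT and lower EE means in ApcMin and Tcf4Het, each with a deposited p of the authors above 0.1. The difference in signed z of YS2 between Tcf4Het and Tcf4Het ApcMin mice had an unadjusted p of 0.00223 and did not pass over all genera and pairs.

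Within single genotypes, no genus passed the Benjamini-Hochberg threshold computed from the authors' p. At an unadjusted p under 0.05 the authors' tables held 3 of 114 genera in WT, 6 of 108 in ApcMin, 0 of 106 in Tcf4Het and 5 of 103 in Tcf4Het ApcMin. Together these are 14 of 431 tests, and all 14 had the higher mean in EE. A share of 0.05 of the tests is 21.6. That number overstates what chance gives, since a genus seen in only a single mouse cannot reach such a p. NE had fewer mice than EE in every genotype. On the linear scale this can favour calls higher in EE, so the one-sided split cannot be read as housing alone. On the log scale, a setting added after the data were seen, 23 calls were higher and 10 lower in EE. They were 6 of 81 genera in WT, 8 of 80 in ApcMin, 6 of 76 in Tcf4Het and 13 of 74 in Tcf4Het ApcMin mice. The log scale leaves out genera with a mean of 0 in NE or EE, and in every genotype more genera were at 0 in NE.

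In WT mice the smallest p belonged to Bradyrhizobium, a soil and water genus also known from reagents, at 0.000587% ± 0.000587 (SEM) in NE and 0.00419% ± 0.000792 in EE in the authors' deposited table. Its NE value came from 1 mouse, since SEM and mean are equal. The unnamed Rikenellaceae genus had 0.779% ± 0.172 in NE and 1.58% ± 0.154 in EE, with an adjusted p of 0.555 from the authors' p. Chryseobacterium had 0.000296% in NE, again from 1 mouse, and 0.0037% ± 0.0012 in EE. Unresolved Burkholderiales, the unnamed S24-7 genus and Bacteroides completed the 6 smallest, all above an unadjusted p of 0.05. Bacteroides, a polysaccharide-degrading genus, had 1.97% ± 0.703 in NE and 5.86% ± 1.88 in EE in the authors' deposited table.

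In ApcMin mice the authors' deposited table gave Odoribacter 0.0873% ± 0.0169 (SEM) in NE and 0.281% ± 0.0429 in EE, the smallest p of that table at 0.00237, with an adjusted p of 0.256. The other 5 were unnamed Ruminococcaceae, Chryseobacterium, the unnamed F16 genus of TM7, other Lachnospiraceae and unnamed Lachnospiraceae, in order of p. Ruminococcaceae and Lachnospiraceae are families known for butyrate producers. Unnamed Ruminococcaceae had 0.748% ± 0.0763 in NE and 1.27% ± 0.159 in EE. Unnamed Lachnospiraceae had 0.846% ± 0.408 and 2.17% ± 0.209, and other Lachnospiraceae 0.195% ± 0.0812 and 0.588% ± 0.140. F16 had 0.294% ± 0.111 in NE and 0.688% ± 0.0976 in EE. Chryseobacterium was rare, with 0.000354% ± 0.000354 in NE, from 1 mouse, and 0.00227% ± 0.000641 in EE.

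In Tcf4Het mice no genus reached an unadjusted p of 0.05 in the authors' deposited table, against 6 on the log scale. The 6 smallest were unnamed Comamonadaceae, Streptococcus, unnamed Xanthomonadaceae, other Lachnospiraceae, unnamed Caulobacteraceae and an unnamed genus of Alphaproteobacteria. Streptococcus had 0.00683% ± 0.00244 (SEM) in NE and 0.000335% ± 0.000335 in EE, the latter from 1 mouse. Other Lachnospiraceae had 0.126% ± 0.0312 in NE and 0.645% ± 0.237 in EE.

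In Tcf4Het ApcMin mice YS2 was followed by other Bradyrhizobiaceae, unnamed Erysipelotrichaceae, the unnamed RF32 genus, Sutterella and unnamed Coriobacteriaceae. The authors' deposited table gave Sutterella, a genus of the Alcaligenaceae, 1.64% ± 1.09 (SEM) in NE and 6.73% ± 1.72 in EE. RF32, of the Alphaproteobacteria, had 0.262% ± 0.110 in NE and 1.35% ± 0.368 in EE. No genus had an unadjusted p under 0.05 in the same direction in 3 or more genotypes, and none in opposite directions in 2.

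Over the 4 genotypes together, 2 of 78 genera passed the combined test, and both rose in EE. Odoribacter, a short-chain fatty acid producer of the Bacteroidales, had the higher mean in EE in 4 of 4 genotypes, by 2.18-fold in WT, 3.22-fold in ApcMin, 7.50-fold in Tcf4Het and 8.48-fold in Tcf4Het ApcMin mice. Its mean log2 ratio was 2.20 ± 0.37 (SE), and the adjusted p from combining the authors' tables was 0.0106. The authors' deposited p for it was under 0.05 only in ApcMin mice, with 0.199 in WT, 0.153 in Tcf4Het and 0.0602 in Tcf4Het ApcMin mice. The unnamed Rikenellaceae genus, also of the Bacteroidales, had the higher mean in EE in 4 of 4 genotypes, by 2.02-fold in WT, 1.42-fold in ApcMin, 2.33-fold in Tcf4Het and 1.74-fold in Tcf4Het ApcMin mice, with a mean log2 ratio of 0.89 ± 0.26 (SE). Its row has an empty genus field and can hold several genera. Its adjusted p from the authors' tables was 0.0403. The authors' deposited p for it was under 0.05 only in WT mice, with 0.321 in ApcMin, 0.282 in Tcf4Het and 0.0561 in Tcf4Het ApcMin mice. Odoribacter did not pass without ApcMin mice (adjusted p of 0.222 from the authors' tables) or without Tcf4Het ApcMin mice (0.0770), and unnamed Rikenellaceae did not pass whichever of the 4 genotypes was left out, with adjusted p between 0.0614 and 0.160. Fisher's method and the genera with a p in 2 or more tables called Odoribacter (0.0299 and 0.0152) and not unnamed Rikenellaceae (0.105 and 0.0579), and weights by sample size and the genera above the median abundance called both. Of the settings chosen after the data were seen, the log scale (0.00025 and 0.0259) and the return of the rows that name no taxon (0.0108 and 0.0413) called both, and the mean difference in percentage points called neither (0.129 and 0.154). Removing the factor that the lower S24-7 share gives, chosen last, left Odoribacter past the threshold (0.0313) and unnamed Rikenellaceae not (0.130).

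**Figure D2:**
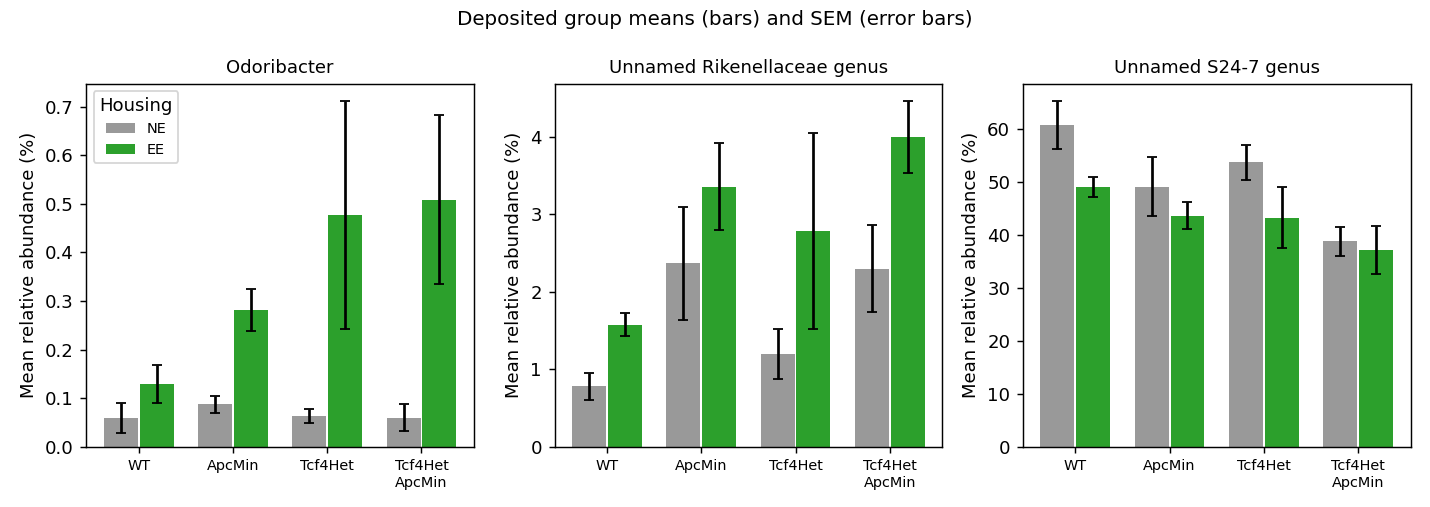
Bars give the deposited mean relative abundance (%) and error bars its SEM for Odoribacter, the unnamed Rikenellaceae genus and the unnamed S24-7 genus, in NE (grey) and EE (green) for each genotype. Odoribacter ranges from 0.0595% to 0.0873% in NE and from 0.129% to 0.508% in EE.

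A further 14 genera had an unadjusted combined p under 0.05 without passing, and 12 of these had the positive sign. With the 2 that passed they make 16 of 78, where a share of 0.05 is 3.9. Shared cages can make the combined p too small, a lower S24-7 share raises the other shares, and genera are not independent. The excess over 3.9 can therefore not be read as housing alone. Other Lachnospiraceae, unnamed Ruminococcaceae and unnamed Lachnospiraceae had higher means in EE in 4 of 4 genotypes, with adjusted p of 0.0525, 0.0580 and 0.0872 from the authors' tables. Their mean log2 ratios were 1.45 ± 0.38, 0.78 ± 0.29 and 1.22 ± 0.34 (SE). Other Lachnospiraceae passed with weights by sample size and among the genera above the median abundance, and all 3 passed on the log scale (chosen after the data were seen). The 2 with lower means were Ureaplasma and unnamed S24-7, the most abundant genus row. Ureaplasma, a wall-less genus of the Tenericutes, had a mean log2 ratio of -1.44 ± 0.42 and also passed on the log scale. Unnamed S24-7 had a mean log2 ratio of -0.21 ± 0.09. S24-7 had 60.7% ± 4.56 (SEM) in NE and 49.0% ± 1.81 in EE in WT mice, and 38.7% ± 2.81 and 37.0% ± 4.52 in Tcf4Het ApcMin mice, in the authors' deposited tables. The unnamed Clostridiales row, second in abundance at 10.7%, had a combined adjusted p of 0.367.

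**Figure D3:**
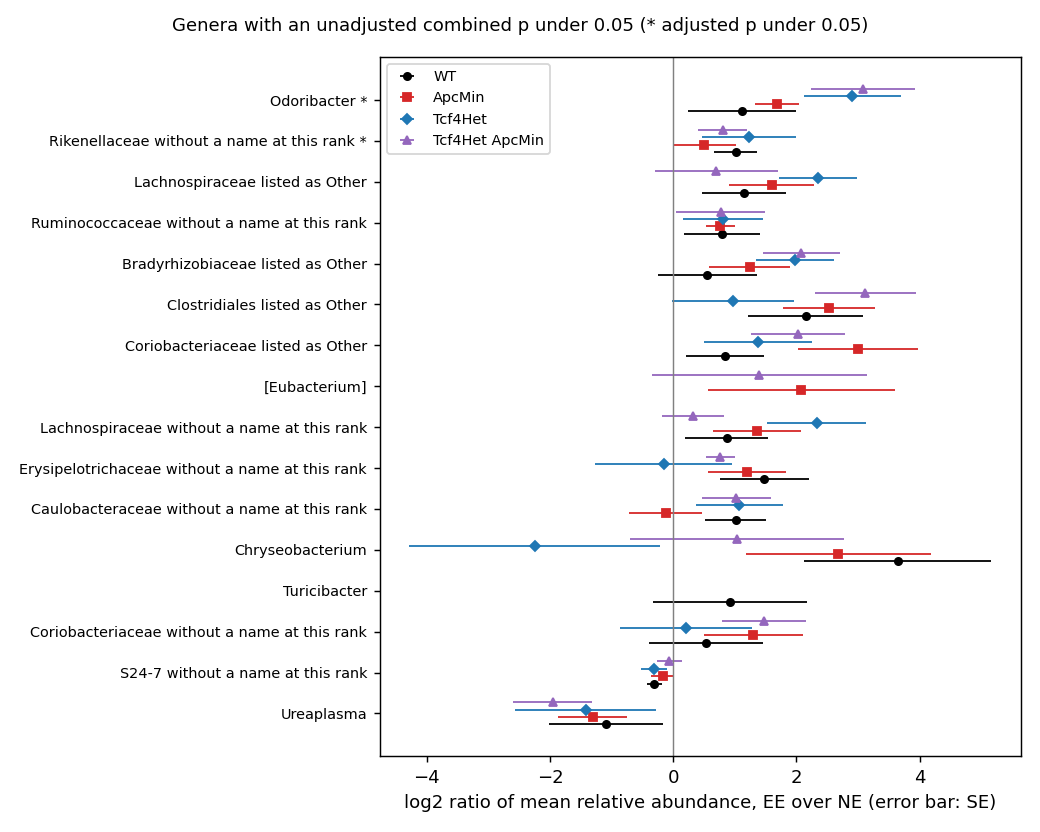
Points give the log2 ratio of mean relative abundance, EE over NE, and bars its SE, per genotype, for the 16 genera with an unadjusted combined p under 0.05. Genera with a mean of 0 in NE have no point for that genotype. Odoribacter and the unnamed Rikenellaceae genus, marked with a star, lie to the right of 0 in all 4 genotypes.

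Genotypes were compared by the difference of their signed z, which weighs the strength of evidence and not the size of the housing effect. None of 530 tests of genera and genotype pairs passed, and none of the 48 tests of taxon lists did. Of the 530, 14 had an unadjusted p under 0.05, where a share of 0.05 is 26.5. These counts do not show that the housing effects were equal. The log2 ratios of the 85 genera measured in both Tcf4Het and Tcf4Het ApcMin mice correlated across genera, with Pearson r = 0.38 (permutation p = 0.0031, adjusted p = 0.0186 over 6 pairs) and Spearman rho = 0.21 (permutation p = 0.107). With the larger pseudocount this pair did not pass (r = 0.24, permutation p adjusted to 0.113). Their signs matched for 55.3% of genera against 52.9% in random pairings. The remaining 5 pairs had Pearson r between -0.07 and 0.29 and did not pass. Of these, ApcMin and Tcf4Het passed with the larger pseudocount (r = 0.44, permutation p adjusted to 0.0024) and among the genera above the median abundance (r = 0.45, adjusted to 0.0258), so which pair passed depended on the setting. In the main setting no Spearman correlation and no share of matching signs passed for any pair.

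Among the lists of taxa, no list differed from random lists of matched abundance in any genotype, in 32 tests with a smallest adjusted p of 0.365. None of the 8 tests of the lists' combined z passed either, with adjusted p between 0.514 and 0.649 against random lists. The combined z was positive for 55 of all 78 genera, against which the counts per list are to be read. Of the 9 members of the Bacteroidales of the mouse gut in the combined test, 7 had the positive sign, and 2 passed over all genera and 2 adjusted over the list alone, Odoribacter and unnamed Rikenellaceae. The summed share of the 10 genera of this list in the tables, most of it S24-7, was 66.1% in NE and 61.2% in EE in WT mice. Of the 11 butyrate-linked Clostridia, 6 had the positive sign, 0 passed over all genera and 3 adjusted over the list alone; Oscillospira, their most abundant genus, had the higher mean in EE in 2 of 4 genotypes, with 2.05% ± 0.540 (SEM) in NE and 2.10% ± 0.319 in EE in WT mice and 3.98% ± 1.20 and 1.79% ± 0.473 in Tcf4Het ApcMin mice in the authors' deposited tables. The list named for the Erysipelotrichi also holds Turicibacter, which the tables place in the Bacilli, and its 5 members in the combined test all had the positive sign, with 0 passing over all genera and 2 adjusted over the list alone. Allobaculum among them had 0.0312% ± 0.0267 in NE and 0.212% ± 0.0889 in EE in Tcf4Het ApcMin mice in the authors' deposited table, and the lower mean in EE in ApcMin mice, with 0.0508% ± 0.0148 and 0.0446% ± 0.0163.

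In the remaining lists no genus passed the combined test over all genera or adjusted over the list alone. Of the 3 mucosa- or IgA-associated genera, Helicobacter and Mucispirillum, both dwellers of the mucus layer, were the most abundant. The authors' deposited table gave Helicobacter 1.47% ± 1.01 (SEM) in NE and 0.811% ± 0.343 in EE in WT mice, and Mucispirillum 0.933% ± 0.557 and 1.07% ± 0.278. In Tcf4Het mice Helicobacter had the higher mean in EE, 1.48% ± 0.991 and 2.00% ± 0.881, and in ApcMin mice Mucispirillum had the lower, 0.996% ± 0.435 and 0.890% ± 0.377, in the authors' deposited tables. Of the lactic acid bacteria and bifidobacteria, Lactobacillus had 5.86% ± 0.823 in NE and 5.10% ± 1.82 in EE in WT mice in the authors' deposited table, and 2.04% ± 0.833 and 3.25% ± 0.640 in ApcMin mice. Of the 9 gut Proteobacteria in the combined test 5 had the positive sign. Of the 5 Tenericutes, TM7 and Deferribacteres 3 had it, and of the 5 other sources of DNA 3 had it. Pseudomonas, of the last list, lay between 0.0154% and 0.0407% in every group. Within single genotypes, 1 genus passed adjusted over the list alone in ApcMin (Odoribacter) and 1 in Tcf4Het ApcMin mice (YS2, in the list of other DNA sources). The colon tumour-associated list had 1 genus in the tables, Enterococcus, listed above 0 only in EE Tcf4Het ApcMin mice at 0.000456%, from 1 mouse.

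Genotypes were set side by side within a housing condition without a test. In NE, Bacteroides had 1.97% ± 0.703 (SEM) in WT, 7.02% ± 1.08 in ApcMin, 3.51% ± 1.15 in Tcf4Het and 14.5% ± 1.88 in Tcf4Het ApcMin mice in the authors' deposited tables. Unnamed S24-7 had 60.7% ± 4.56, 49.1% ± 5.54, 53.6% ± 3.38 and 38.7% ± 2.81 in the same order. In EE, Bacteroides had 5.86% ± 1.88, 7.61% ± 0.501, 6.29% ± 1.71 and 13.1% ± 2.30.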

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

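Alternatives marked as added were chosen after the data were seen. In WT, ApcMin and Tcf4Het mice, 0 genera passed under the abundance filter, the Benjamini-Yekutieli and Bonferroni adjustments, a threshold of 0.1, merged rows, all ranks together, the family rank (added) and the log scale (added). In Tcf4Het ApcMin mice the count rose from 0 to 1 with the genera above the median abundance and to 1 at a threshold of 0.1. It rose to 1 at the family rank (added) and to 5 over all rows of the 5 ranks. Those 5 were all of the YS2 lineage, nested ranks with nearly the same value, so they do not count as separate taxa. At an unadjusted p under 0.05 the log scale (added) moved the count from 3 to 6 in WT, from 6 to 8 in ApcMin, from 0 to 6 in Tcf4Het and from 5 to 13 in Tcf4Het ApcMin mice. It covers only the genera above 0 in both housing conditions. The combined count of 2 fell to 1 with Fisher's method by direction, to 1 without WT, to 0 without ApcMin, to 1 without Tcf4Het, to 0 without Tcf4Het ApcMin, to 1 with taxa in 2 or more tables, to 1 with the closure factor of S24-7 removed (added) and to 0 for the mean difference over the genotypes (added). Wherever 1 remained it was Odoribacter. The count was 3 with weights by sample size and 3 among the genera above the median abundance, with other Lachnospiraceae as the one gained. It was 10 on the log scale (added, over 66 genera) and 10 at a threshold of 0.1 (added). Over these settings the adjusted p of Odoribacter ran from 0.00025 to 0.222 and that of unnamed Rikenellaceae from 0.0259 to 0.160. Apart from the closure factor, the cause of these shifts was not tested. The number of genotype pairs with a Pearson correlation past the threshold was 1, and 2 with the genera above the median abundance, where ApcMin and Tcf4Het also passed (r = 0.45, adjusted p = 0.0258). With the larger pseudocount the count of 1 stood for another pair, ApcMin and Tcf4Het, with r = 0.44, while Tcf4Het and Tcf4Het ApcMin had r = 0.24 and did not pass (adjusted p = 0.113). The number of phyla with one direction in all genotypes was 2, and 1 with the centred log ratio, OD1 in place of Bacteroidetes and Actinobacteria. The median log2 ratio of the genera above 0 in both housing conditions was 0.50 in WT, 0.07 in ApcMin, 0.29 in Tcf4Het and 0.29 in Tcf4Het ApcMin mice. Interaction and list counts of 0 held under every alternative run. Count models, other size factors, leaving out single mice and diversity at other depths were not run, since they need values per mouse. No paired analysis was run, because NE and EE mice were different animals and the columns hold group means. Depth is unknown, and genera listed at 0 or in 1 mouse have no error of their own.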

Other observations

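The tests in this part were written down after the patterns had been seen and before their own values were computed. Those with the closure factor removed from every genus were added last, after the results of the other tests had been seen. A direction shared by rare taxa deserves a look first. Ureaplasma, a genus of the Tenericutes, had a lower mean in EE in 4 of 4 genotypes, by 2.13-fold in WT, 2.47-fold in ApcMin, 2.68-fold in Tcf4Het and 3.88-fold in Tcf4Het ApcMin mice, without passing the combined test (adjusted p = 0.0988 from the authors' tables). On the log scale and at a threshold of 0.1, both chosen after the data were seen, it was among the genera called. Turicibacter, which the tables place in the Bacilli, was listed at 0 in NE in ApcMin, Tcf4Het and Tcf4Het ApcMin mice. In EE the authors' deposited tables gave it 0.0162% ± 0.0125 (SEM), 0.0291% ± 0.023 and 0.050% ± 0.0312 in the same order. In WT mice it had 0.00133% ± 0.000771 in NE and 0.00253% ± 0.00163 in EE. The authors' deposited p for it was above 0.1 in 4 of 4 genotypes, and its combined adjusted p was 0.176. Both were named after their values were seen.

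All 14 genus calls at an unadjusted p under 0.05 had the higher mean in EE. Closure was tested first, since a lower S24-7 share raises every other share by one factor, between 1.03 and 1.30. The median log2 ratio of the 14 calls without that factor, 1.77, decides nothing, since the calls were picked by the size of their difference. With the factor removed from every genus before the test, 11 calls were higher and 0 lower in EE (100% higher). This argues against that factor as the whole cause of the one-sided split. The retest kept the linear scale, and it could change little in Tcf4Het ApcMin mice, where the factor was 1.03. Closure from other taxa was not removed and stays open. The linear scale stays open. In that explanation the group with the higher mean has the larger SEM and NE has fewer mice, which can favour calls higher in EE. On the log scale 69.7% of calls were higher in EE, between the 60% and 80% that would have decided it. The log scale left out genera with a mean of 0 in NE or EE, more of them at 0 in NE, so this share is not over the same genera. Cage effects cannot be told apart from housing, because 0 samples carry a cage label, and an effect of housing itself stays open as untested.

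Odoribacter rose in EE over the 4 genotypes. With the closure factor of S24-7 removed from every genus it still passed the combined test over all genera (adjusted p = 0.0313 from the authors' tables). The factor was only 1.11 in ApcMin and 1.03 in Tcf4Het ApcMin mice, where the deposited p of Odoribacter was smallest. Little was therefore removed there. Passing argues against that factor as the whole cause, while closure from other taxa was not removed and stays open. In Tcf4Het ApcMin mice the median log2 ratio over genera was 0.29, against a log2 factor of 0.04. Odoribacter was picked by its combined p, so the difference that is left can be too large. Its mean log2 ratio without the factor was 1.99 ± 0.38 (SE). A single mouse per group cannot set the direction in 3 of the 4 genotypes, because the bounds on the means without any 1 mouse do not meet. In WT mice they meet, at 0.0900% for EE and 0.0907% for NE, so the explanation that a single mouse per group sets the difference stays open there. Cage and housing remain open for the rest.

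The unnamed Rikenellaceae genus no longer passed with the closure factor removed from every genus (adjusted p = 0.130 from the authors' tables). Its mean log2 ratio went from 0.89 ± 0.26 (SE) to 0.67 ± 0.28, so the call ended through a smaller difference, and closure stays open as part of it because the genus was picked by that difference. The direction held without any 1 mouse of each group in 3 of the 4 genotypes, and the explanation that a single mouse per group sets the difference stays open for ApcMin mice. In Tcf4Het mice the bounds were 1.522% and 1.517%, a margin smaller than either SEM.

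Turning the sign of whole genotypes gave 8 arrangements of the combined test. The real one called 2 genera, the highest of the others called 0, and 1 arrangement, the real one, called as many. With 8 arrangements a share under 0.05 cannot be reached.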
